A study of Arabidopsis thaliana with 88 samples.

How the data were processed

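Expression was measured with Agilent 1-colour arrays (Cy3) on whole 10-day-old Arabidopsis seedlings of Col-0 wild type and of a line in which estradiol induces WIND1, an AP2/ERF transcription factor of wound-induced cell reprogramming. Per the labels' protocols, seedlings grew on MS agar and were given 10 µM estradiol or DMSO as a mock treatment, RNA was purified with an RNeasy kit and labelled with a Low Input Quick Amp kit. The 88 arrays fell into 22 groups of 4: each line untreated at 0 h, and each line under DMSO or estradiol at 1, 3, 6, 12 and 24 h. The labels do not say whether the 4 replicates of a group were separate cultures, so each p-value measures only the spread between these arrays.

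Per the file headers, Agilent Feature Extraction 9.1.3.1 turned each scan into a processed signal (an intensity), background-subtracted and detrended within the array, for 45220 spots. The raw median intensity of spot and local background is in the same deposited scanner files, and the spot's mean intensity is not. The deposited series value table of the authors is on a natural log scale (ln), since the slope of its differences between arrays against those of the log2 processed signal had a median of 0.709 over 86 arrays, each set against 1 array, range 0.683 to 0.723, where a change of log base alone gives 0.693. Its columns all had the same median, which quantile normalisation leaves and centring on the median leaves too. They also held an added constant whose value is not given in the sources used here. Values here therefore came from the scanner files, and the table served as an alternative.

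Each array's log2 processed signal was centred on its 75th percentile. Of 43603 probes that were not controls, 34185 carried 1 locus and 9418 none. For the 6874 loci with several probes the brightest probe over all arrays was taken, except for WIND1, whose 6 probes were each reported. Of 25347 loci, 21501 with a probe well above background on all arrays of at least 1 group were tested. Symbols came from a table of the TAIR10.1 assembly, used for names only.

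One linear model with 22 group means (66 residual degrees of freedom) was fitted with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 for handling and plots. Contrasts were estradiol against DMSO at each time in the induced line and in wild type, the difference between these effects, the lines at 0 h, the lines over the DMSO arrays, and the wild-type DMSO times against 0 h. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and every adjusted p in the text is from limma. For the WIND1 probes and the homologues of WIND1 the fit and the adjustment were over all 43603 probes. Changes are log2 ± standard error (SE) of 4 against 4 arrays unless stated. Where 1 group lay at background on all 4 arrays, the change is a lower bound, computed against the background level and written as at least N-fold.

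On simulated data with 200 changed genes placed in the 6 h arrays of the induced line, 46.3%, 83.6% and 90.9% were recovered at log2 changes of 0.5, 1 and 2. The difference contrast recovered 14.9%, 70.1% and 81.8%. Among 21306 genes the unchanged ones gave 7 and 8 false calls. When each slide was instead given a random shift per gene, as large as the wild-type effects allow, and no treatment effect, the fit with the error between arrays made 2994 false calls at 6 h. With the error between slides limma made 0. Counts of calls therefore hold for these slides. For the induced line at each time and for the lines at 0 h the count from the fit between slides is given beside them. That fit pools the wild-type slides of a time, and no such fit was run for wild type, the difference, the DMSO arrays of the lines or the time course.

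The gene lists, the contrasts, the list of other settings and the rule for named genes were fixed before the data were examined. The rule took WIND1 and its 3 homologues. It took, at each time, the 5 largest rises and 5 largest falls among genes called in the induced line and in the difference with 1 sign, whose 4 estradiol arrays all lay on 1 side of the 4 DMSO arrays. For other comparisons it took the 5 largest called rises and falls without overlap, or the 5 largest ranges of the time course. Any list member could be named, with at least the 3 of smallest adjusted p in the difference.

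There were 23 lists with 374 members. The 22 lists tested were regeneration transcription factors, cytokinin response, cytokinin metabolism, auxin response and synthesis, xylem, phloem and procambium, jasmonate, salicylic acid and systemic resistance, pattern-triggered immunity and camalexin, ethylene, wound and touch handling, cell cycle, suberin, cuticular wax, abscisic acid and dehydration, embryo and seed maturation, photosynthesis, root tissue, circadian clock, xenobiotic detoxification, heat shock and senescence. The WIND family list had 1 matched member and was not tested, 8 members were left out of the list tests because the symbol given at their locus differed, and 4 had no probe. Lists were tested with cameraPR in the difference contrasts (preset correlation 0.01, adjusted over 110 tests), and again with a correlation estimated per list. Between the lines they were tested in the same 2 ways, adjusted over the 22 lists of 3 comparisons.

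Each of the 22 slides held 1 group, and the slides were scanned on 5 days. The induced line's slides of 1, 3 and 6 h, scanned on 1 day, had another extraction protocol name in the file headers than all other slides. The wild-type groups of a time shared a day at 6 and 24 h, the induced line's groups at 1, 3, 6 and 12 h, and the DMSO groups of both lines at 24 h alone. Group and slide therefore cannot be told apart in any single contrast, and group and scan day cannot in the others. A model with the error taken between slides (wild-type estradiol and DMSO slides of a time as replicate slides, 5 residual degrees of freedom) and a model with scan day as a block (wild type pooled within a time) were added after the data were seen. The day terms of the latter rest on the wild-type slides of 1, 3 and 12 h, where estradiol and DMSO slides had different scan days. Replicate numbers did not pair arrays throughout: over 44 pairs the correlation of residuals was -0.373 to 0.473, median 0.0671. In 18 pairs the array of the same number was the best match. In the induced line at 12 h this held for all 4 (0.37, 0.314, 0.393 and 0.076). Replicate number entered as a block only as an alternative. That block is shared by all groups and cannot take up pairing within a single time.

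The alternatives were quantile normalisation, normexp background correction (offset 50, on median intensity), the series value table, no filter on dim probes, the mean over a gene's probes, a fit on the arrays of 1 time, a replicate block, another variance prior, a 2-fold threshold, an estimated correlation and leaving out each array. The 9418 probes without a locus were left out of the comparisons, other than the fit of all probes for WIND1 and its homologues.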

Results

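The data were 88 arrays in 22 groups of 4, from wild-type seedlings and seedlings of an estradiol-inducible WIND1 line, untreated or 1, 3, 6, 12 and 24 h after DMSO or estradiol. The median signal of an array was 63.9 to 911, and 65.4% to 82.3% of its spots lay well above background. The lowest median was that of replicate 2 of the induced line's 1 h DMSO arrays, against 291 to 338 in the other 3 arrays of its group. The lowest percentage was that of replicate 1 of the induced line's 1 h estradiol arrays. The 4 arrays and the 1 slide per group both limit the precision. The median SE of a log2 change was 0.141, from the spread between arrays within slides. Differences between slides are left out of it: the 5 wild-type estradiol effects, each between slides, had a median root mean square of 0.243 (log2).

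The first comparison asks how far the inducer raised WIND1 (AT1G78080). In the induced line, 3 of its 6 probes rose at every time. Probe 1 rose by 1.69 ± 0.12 at 1 h, 2.12 at 3 h, 2.02 at 6 h, 2.62 at 12 h and 2.70 at 24 h (log2, adjusted p from 6.01e-17 down to 2.65e-29). Probe 2 rose by 1.35 ± 0.17 at 1 h and 2.52 at 24 h, and probe 6 by 1.84 ± 0.13 and 2.75. Probe 3 rose by 0.69 ± 0.19 at 1 h, 0.78 at 6 h, 1.53 at 12 h and 1.30 at 24 h, with 0.12 at 3 h (adjusted p = 0.727). The brightest probe, probe 4, was not called at any time in this line (-0.14 to 0.32, and 0.39 and called at 12 h without DMSO replicate 1), and probe 5 was called at 1 h alone (0.51 ± 0.17). In wild type, probes 1, 2 and 6 were not called at any time (-0.17 to 0.36). Wild-type probe 3 fell by 0.49 at 1 h and 0.55 at 3 h, and probe 4 rose by 0.38 at 12 h. The position of each probe in the transcript is not given in the sources used here, so induced and endogenous WIND1 transcripts were not told apart. Of the 3 homologues, AT1G22190 fell by 0.59 ± 0.15 in the induced line at 24 h (adjusted p = 0.00115) and rose by 0.60 in wild type at 6 h. AT1G36060 and the dim AT5G65130 were not called after estradiol in either line.

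**Figure D1:**
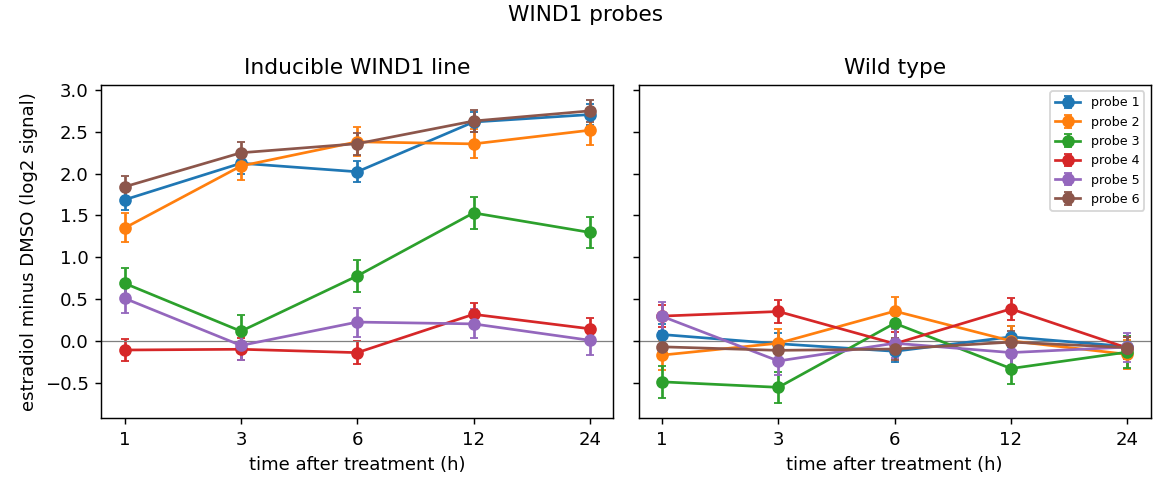
Estradiol minus DMSO (log2 signal) for the 6 WIND1 probes against hours of treatment (times evenly spaced), induced line left and wild type right. Points are means of 4 against 4 arrays with SE bars, and in the induced line probes 1, 2 and 6 lie between 1.35 and 2.75 at every time.

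The next comparisons ask which other genes estradiol changed in the induced line at each time, and whether the change differed from that in wild type. At 1 h the largest rises were those of the ERF gene ERF53 (AT2G20880, 3.65 ± 0.38, with 0.98 in wild type), ORA47 (AT1G74930, 3.54 ± 0.46), AT2G44130 (3.24 ± 0.20, with 2.25 in wild type), the protein phosphatase HAI2 (AT1G07430, at least 3.24-fold) and RAS1 (AT1G09950, at least 2.12-fold). HAI2 lay above background on 2 of its 4 estradiol arrays and RAS1 on 3, and ORA47 on 2 of its 4 DMSO arrays. The largest falls were those of MYB40 (-2.67 ± 0.43, above background on 1 of 4 estradiol arrays), AT2G43880 (-2.42 ± 0.40), the expansin EXPA17 (-2.38 ± 0.33, with -0.89 in wild type), AT1G11655 (-2.19 ± 0.43) and MES15 (-2.14 ± 0.49, also on 1 of 4). In the jasmonate list, 10 of 21 members rose in the induced line and JAZ7 (2.58 ± 0.51) and JAZ10 (1.84 ± 0.46) also passed the difference test, while AOC3 had 0.57 and was not called (0.92 and called without estradiol replicate 1). The list was called in the difference (median 0.44, adjusted p = 0.0175, with 1 member adjusted over the list alone). That call was lost at adjusted p = 0.955 with an estimated correlation, and without replicate 3 of the estradiol arrays, where the median was 0.094. JAZ10 was not called without replicate 2 of the DMSO arrays (1.19).

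Of the 11 abscisic acid and dehydration genes, 7 rose in the induced line at 1 h (9 adjusted over the list alone), among them LTI30 (1.90 ± 0.28), ABI2 (0.43 ± 0.14) and HAI1 (1.15 ± 0.30), while RAB18 had 0.07. That list was not called in the difference (adjusted p = 0.615), and 5 members also rose in wild type. Against the mean wild-type effect of 6 and 24 h it was called (0.69). Of the 16 genes of the wound and touch list, 8 rose in the induced line (9 adjusted over the list alone) and 3 in wild type, and the difference was not called (median 0.39, adjusted p = 0.095). It was called without wild-type estradiol replicate 1 (0.50) or induced-line estradiol replicate 1 (0.46) or 4 (0.44), with normexp (0.31), in a fit on the arrays of that time alone, and against the mean wild-type effect of 6 and 24 h (0.63). Its members of smallest adjusted p in the difference were EXO (0.33 in the induced line), PHI-1 (0.99) and TCH4 (0.45), none called in this line. The photosynthesis list was lower in the difference (median -0.75, adjusted p = 1.94e-07, 14 members lower and 16 adjusted over the list alone). RBCS3B (-0.28 against 0.79), PSBO1 (-0.30 against 0.76) and RBCS1B (-0.40 against 0.77) were not called in the induced line, and 14 members rose in wild type. Without DMSO replicate 4 these 3 were called lower (-0.41, -0.46 and -0.56), and RBCS1B also without DMSO replicate 1 (-0.50) or 3 (-0.52). This call was lost at adjusted p = 0.955 with an estimated correlation, under quantile normalisation (median -0.01), and against the mean wild-type effect of 6 and 24 h (-0.05).

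In all, 5676 genes were called in the induced line at 1 h, 2495 higher and 3181 lower (44% higher, and 65.1% of the 504 with at least a 2-fold change). In a fit on the arrays of that time alone there were 1013, and 3116 with normexp. Without the weak replicate 2 of the DMSO arrays there were 1570, and ABI2 (0.27) and HAI1 (0.78) were not called. ABI2 was also not called without estradiol replicate 1 (0.40) or 3 (0.38). The difference was called for 4117 genes, 35.7% of them higher, with 46.4% higher under quantile normalisation and 46.1% in the series value table. With normexp there were 2570, in a fit on the arrays of that time alone 1118, and against the mean wild-type effect of 6 and 24 h 6299. With the same sign in both there were 1653 genes. With the error taken between slides, 4 genes were called in the induced line at 1 h, HAI2 and MYB40 among them. The other genes named above for the largest rises and falls were not. Among these, ERF53 had adjusted p = 0.234, ORA47 adjusted p = 0.324 and AT2G44130 adjusted p = 0.399.

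At 3 h, GulLO1 (AT1G32300), a relative of gulonolactone oxidase, was at least 397-fold higher and AT5G17500 at least 53.6-fold higher in the estradiol arrays of the induced line, each above background on all 4 estradiol and on 0 of 4 DMSO arrays. AT5G61620 rose by 6.68 ± 0.35 and the GDSL lipase GLIP6 (AT1G71120) by 6.53 ± 0.28, measured above background on 2 and 1 of 4 DMSO arrays, and the polygalacturonase PGA4 (AT1G02790) was at least 11-fold higher. In wild type these 5 genes were not called at 3 h (adjusted p = 0.206 to 0.718). The largest falls were those of AT4G16270 (-3.45 ± 0.32), AT1G05660 (-3.21 ± 0.49), AT1G05650 (at least 1.7-fold), CYP702A2 (-2.76 ± 0.42) and UMAMIT4 (-2.37 ± 0.30). Among list members, the homeobox gene WOX13 rose by 1.49 ± 0.10, the cytokinin oxidase CKX4 by 2.44 ± 0.17, the vessel regulators VND2 by 1.32 ± 0.12 and VND7 by 1.12 ± 0.19, the phloem sucrose carrier SUC2 by 0.91 ± 0.13 and the procambium gene HB-8 by 0.54 ± 0.10. Each of these 6 passed the difference test. In the cell cycle list, 16 of 21 members fell in the induced line (18 adjusted over the list alone, median -0.57), among them CDKB2;1 (-0.72 ± 0.14), CYCA1;1 (-0.93 ± 0.17) and CYCD1;1 (-0.53 ± 0.15). In wild type 9 members fell, and the list was not called in the difference (adjusted p = 0.206), but was against the mean wild-type effect of 6 and 24 h (-0.83).

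At 3 h the induced line had 3981 calls, 1794 higher and 2187 lower (45.1% higher), and 2607 without replicate 4 of the estradiol arrays. With normexp there were 2217, 54.7% of them higher, and of the 674 with at least a 2-fold change 70.6% were higher. The difference was called for 1208 genes, 800 higher and 408 lower, of which 759 were also called with the same sign in the induced line. With normexp 586 were called, and against the mean wild-type effect of 6 and 24 h 4976, 2089 higher and 2887 lower. By cameraPR 0 of 22 lists were called in the difference at this time, and 3 had an unadjusted p under 0.05. Single arrays changed this. The xylem list was called without DMSO replicate 2 or 4 or estradiol replicate 2 of the induced line or estradiol replicate 3 or 4 of wild type (0.12 to 0.18). The wound and touch list was called without wild-type DMSO replicate 2 (0.72) or induced-line estradiol replicate 2 (0.56), and the immunity list without wild-type DMSO replicate 2 or estradiol replicate 1 (0.42 in both). The root list was called without wild-type estradiol replicate 1 (-0.56) and the suberin list without induced-line estradiol replicate 1 (-0.55). With the error taken between slides 139 genes were called, 120 of them higher, and of the genes above PGA4, AT1G05650 and CYP702A2 were not.

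At 6 h, GulLO1 was at least 902-fold and AT5G17500 at least 134-fold higher, and AT5G61620 (8.36 ± 0.35), GLIP6 (7.19 ± 0.28) and PGA4 (7.13 ± 0.75) rose, with 3, 1 and 1 of their DMSO arrays above background. In wild type GulLO1 was called lower at 6 h (adjusted p = 0.00249), above background on 0 of 4 estradiol and 2 of 4 DMSO arrays, too close to background for a bound, and the other 4 were not called. The largest falls were those of AT1G05660 (-4.84 ± 0.49) and AT4G16270 (-4.63 ± 0.32), each above background on 2 of 4 estradiol arrays, the root-hair regulator RSL2 (AT4G33880, -3.94 ± 0.47), AT5G60060 (at least 8.6-fold) and AT2G39040 (-3.79 ± 0.41). In the xylem list, 6 of 20 members rose in the induced line and the same number passed the difference test, also when adjusted over the list alone. The members that did both numbered 5. VND2 rose by 2.19 ± 0.12, VND7 by 1.78 ± 0.19, VND6 by 1.17 ± 0.15 and MYB46, which acts downstream of them in wall formation, by 0.95 ± 0.14. The list's median difference was 0.29 (adjusted p = 0.00169, and adjusted p = 0.955 with an estimated correlation). In the jasmonate list 9 of 21 members rose, and 7 passed the difference test (7 adjusted over the list alone), led by the allene oxide cyclases AOC1 (2.62 ± 0.30), AOC2 (2.11 ± 0.30) and AOC3 (2.54 ± 0.32). Its median difference was 1.18 (adjusted p = 1.29e-05, and adjusted p = 0.955 with an estimated correlation).

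The cell cycle list was lower in the difference at 6 h (median -0.58, 11 members lower, 1 higher and 13 lower adjusted over the list alone, adjusted p = 0.000515, and adjusted p = 0.955 with an estimated correlation). In the induced line CYCD3;1 (-0.14), CYCB1;2 (-0.18) and CDKB2;1 (-0.15) were not called, and in wild type they had 0.83, 0.84 and 0.62. Of the 13 suberin genes, 8 fell in the induced line (8 adjusted over the list alone, median -1.0), among them ASFT (-1.08 ± 0.23), ABCG20 (-2.09 ± 0.33) and CYP86B1 (-1.85 ± 0.35), and the list was not called in the difference (adjusted p = 0.154). It was called without wild-type DMSO replicate 2 (-0.82) or induced-line DMSO replicate 4 (-0.88), with the mean over probes (-0.71) and against the mean wild-type effect of 6 and 24 h (-0.79). The endodermis genes CASP1 (-1.93 ± 0.40) and CASP2 (-1.26 ± 0.28) of the root list fell, as did MYB36 (-0.94 ± 0.24), which was not called without replicate 3 of the estradiol arrays (-0.51). ERF115, a regulator of stem cell division, was at least 2.62-fold higher and WOX13 rose by 2.08 ± 0.10, while SCR had -0.04. CRF6 rose by 1.57 ± 0.18, and the response regulators ARR9 (-0.63 ± 0.13) and ARR4 (-0.65 ± 0.16) fell.

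At 6 h 4953 genes were called in the induced line, 1810 higher and 3143 lower, and 4363 in the difference, of which 2415 had the same sign in both. With normexp there were 3275 and 2706. Of the 1455 genes differing by at least 2-fold 51.1% were higher, against 42.3% of the 4363. With the error taken between slides 676 genes were called in the induced line, 343 higher and 333 lower, all 10 genes with the largest changes among them.

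At 12 h GulLO1 was at least 1630-fold, AT5G17500 at least 473-fold, AT1G32280 at least 139-fold and AT1G04670 at least 73.4-fold higher, each above background on 4 of 4 estradiol and 0 of 4 DMSO arrays, and PGA4 rose by 8.05 ± 0.75. The largest falls were those of AT5G46890 (at least 10.2-fold), AT1G05660 (-5.08 ± 0.49, above background on 2 of 4 estradiol arrays), AT4G16270 (-4.35 ± 0.32), AT1G05650 (at least 4.34-fold) and CER4 (AT4G33790), a reductase that makes the primary alcohols of wax (-4.22 ± 0.31). In the xylem list 18 of 20 members rose and 1 fell, and 16 passed the difference test (17 adjusted over the list alone). VND7 rose by 3.06 ± 0.19, VND2 by 2.64 ± 0.12, MYB46 by 2.49 ± 0.14 and the xylem protease XCP1 by 1.87 ± 0.13. The median difference was 1.16 (adjusted p = 1.05e-17, and adjusted p = 0.0496 with an estimated correlation). In the jasmonate list 17 of 21 members rose and 10 passed the difference test (13 adjusted over the list alone), with AOC1 at 3.77 ± 0.30, AOC2 at 2.66 ± 0.30 and LOX4 at 1.83 ± 0.38. Its median difference was 1.18 (adjusted p = 1.49e-07, and adjusted p = 0.955 with an estimated correlation).

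In the cell cycle list 19 of 21 members fell at 12 h and 17 passed the difference test (19 adjusted over the list alone), among them the cytokinesis syntaxin KN (-0.99 ± 0.17), CDKB1;2 (-0.89 ± 0.17) and CYCA1;1 (-1.01 ± 0.17). Its median difference was -0.95 (adjusted p = 1.94e-07, and adjusted p = 0.955 with an estimated correlation), and with the error taken between slides 1 member fell. The salicylic acid list had 12 of 22 members lower and 2 higher in the induced line (12 lower and 3 higher adjusted over the list alone), with WRKY54 at -1.86 ± 0.35, WRKY70 at -1.14 ± 0.32 and WRKY18 at 1.83 ± 0.34. It was not called in the difference (adjusted p = 0.541). The abscisic acid list was called in the difference (median 0.51, 5 higher and 1 lower, also adjusted over the list alone, adjusted p = 0.0477, and adjusted p = 0.955 with an estimated correlation). Its leading members were NCED3 (1.28 ± 0.24), ABI1 (0.54 ± 0.12) and LTI30 (1.83 ± 0.28), RAB18 fell by 0.90 (0.80 higher with the mean over its probes), and the list's call was lost without each of 9 single arrays and under quantile normalisation. The photosynthesis list was lower in the difference (median -0.52, 6 members lower and 10 adjusted over the list alone, adjusted p = 0.0252, and adjusted p = 0.955 with an estimated correlation). LHCB6 (-0.38 ± 0.14) and PSAD-1 (-0.38 ± 0.12) fell, no longer called without replicate 2 of the DMSO arrays (-0.24 and -0.29) or replicate 4 of the estradiol arrays (-0.27 and -0.30), and PSBO1 was not called in the induced line and had 0.68 in wild type. That list's call was lost without each of 6 single arrays, and its median was 0.12 against the mean wild-type effect of 6 and 24 h. WOX13 (2.12 ± 0.10), ERF115 (at least 12.1-fold) and LBD18 (1.47 ± 0.19) rose. CKX4 rose by 2.91 ± 0.17 and CKX1 fell by 2.80 (above background on 2 of 4 estradiol arrays), and the auxin-conjugating enzymes GH3.3 (-1.07 ± 0.29), GH3.5 (-0.59 ± 0.13) and GH3.2 (-1.40 ± 0.24) fell, GH3.3 not being called without replicate 3 of the estradiol arrays (-0.72).

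At 12 h 7740 genes were called in the induced line, 2730 higher and 5010 lower (35.3% higher, and 22.1% with normexp background correction). The difference was called for 5626 genes, 36.8% of them higher, and for 10221, 16.2% of them higher, with normexp, which moved the median of all genes by 0.13 in wild type and by -0.17 in the difference. Of these, 4257 had the same sign in both. With the error taken between slides 956 genes were called, 701 higher and 255 lower, all 10 genes with the largest changes among them.

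At 24 h PGA4 was at least 538-fold, AT5G17500 at least 355-fold and GulLO1 at least 258-fold higher, and AT2G30830 rose by 8.68 ± 0.52 and AT5G61620 by 8.47 ± 0.35. The largest falls were those of the polygalacturonase PGAZAT (AT2G41850, -4.84 ± 0.74, above background on 1 of 4 estradiol arrays), AT4G16270 (at least 18.3-fold), the systemic-resistance gene FMO1 (AT1G19250, -4.44 ± 0.60, on 2 of 4), AT1G05660 (-4.12 ± 0.49) and AT5G43590 (at least 3.88-fold). These 10 genes were also called with the error taken between slides. In the xylem list 18 of 20 members rose, 1 fell, and the same numbers passed the difference test, also adjusted over the list alone. VND7 rose by 3.3 ± 0.19, VND2 by 3.25 ± 0.12, XCP1 by 2.43 ± 0.13, BFN1 by 2.35 ± 0.16, the metacaspase MC9 by 2.26 ± 0.15, MYB46 by 2.18 ± 0.14 and LBD30 by 2.16 ± 0.15, and the fibre regulator SND1, above background on 1 of 4 estradiol and 2 of 4 DMSO arrays, fell by 1.99. The median difference was 1.64 (adjusted p = 1.36e-25, and adjusted p = 0.00895 with an estimated correlation). With scan day as a block the median change of the list in the induced line was 1.74, against 1.53 without it.

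**Figure D2:**
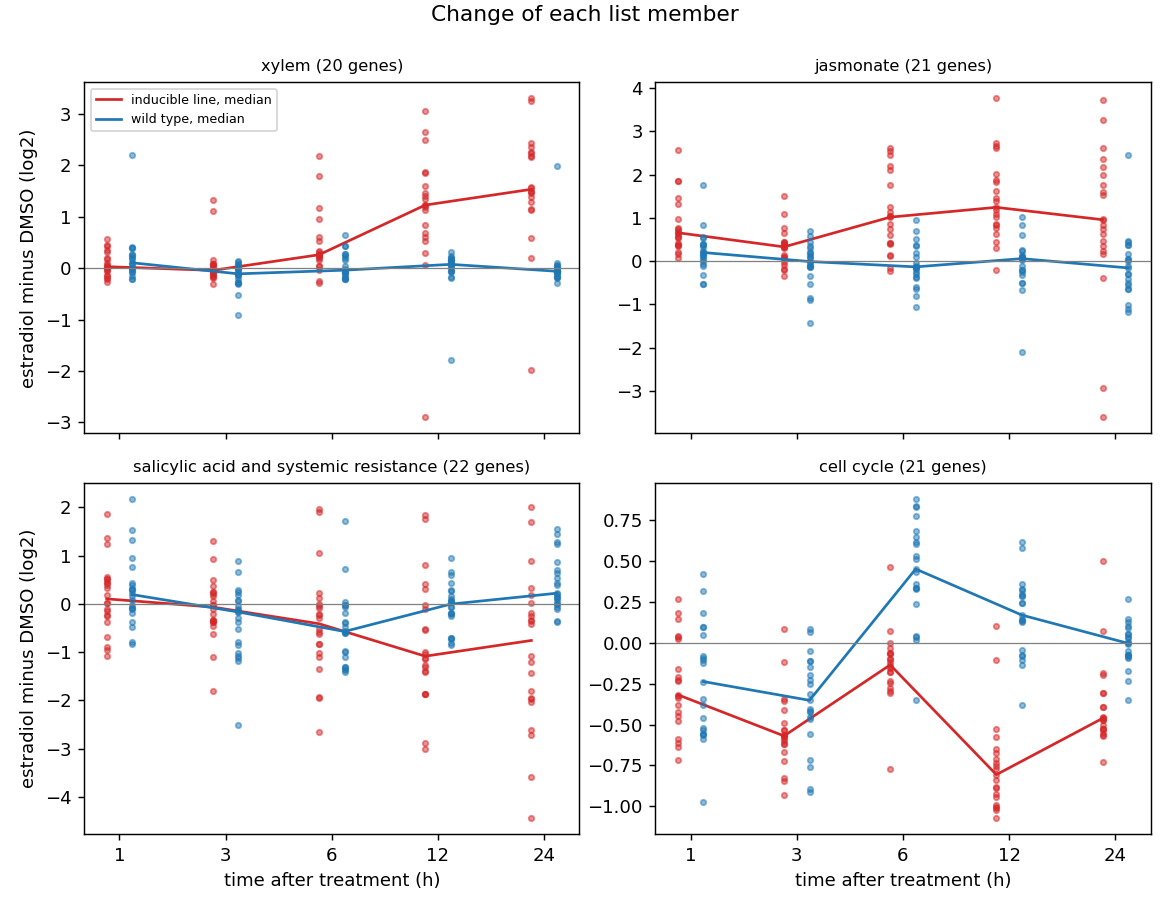
Estradiol minus DMSO (log2 signal) of the members of 4 lists (points) and their medians (lines) against hours of treatment (times evenly spaced), induced line in red and wild type in blue, 4 against 4 arrays, no error bars, a separate vertical scale in each panel. The induced-line median of the 20 xylem genes was 0.26 at 6 h, 1.22 at 12 h and 1.53 at 24 h.

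The jasmonate list had 13 members higher and 1 lower at 24 h, and the same numbers passed the difference test (15 higher and 1 lower adjusted over the list alone). AOC2 rose by 3.71 ± 0.30, AOC1 by 3.26 ± 0.30 and LOX2 by 1.61 ± 0.24. Its median difference was 1.80 (adjusted p = 3.56e-06, and adjusted p = 0.955 with an estimated correlation). In the salicylic acid list 11 of 22 members fell and 2 rose (the same adjusted over the list alone), and in the difference 11 were lower and 1 higher (13 and 2 adjusted over the list alone). FMO1 fell by 4.44, ALD1, which acts in the same pathway, was at least 2.75-fold lower, PBS3 fell by 2.71 and WRKY70 by 1.98, while WRKY18 rose by 2.02. The list's median difference was -1.40 (adjusted p = 0.0167, and adjusted p = 0.955 with an estimated correlation). With scan day as a block the list's median in the induced line was -0.49 against -0.76 without it. The list was then not called by cameraPR (adjusted p = 0.186), nor was WRKY70 called (-0.44).

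Of 22 regeneration transcription factors, 9 rose and 2 fell at 24 h (also adjusted over the list alone), and in the difference 6 were higher and 2 lower (7 and 2 adjusted over the list alone). WOX13 rose by 2.29 ± 0.10, ERF115 was at least 6.54-fold higher, and LBD18 (1.83 ± 0.19), WOX5 (1.72 ± 0.27), PLT5 (1.43 ± 0.16) and SHR (0.55 ± 0.11) rose. The median difference was 0.27 (adjusted p = 0.0109, and adjusted p = 0.955 with an estimated correlation). Of 9 wax genes, 5 were higher and 1 lower in the difference (6 and 1 adjusted over the list alone). MAH1 was at least 11.2-fold and the wax ester synthase WSD1 at least 9.74-fold higher, and CER4 fell by 2.17. The median difference was 0.45 (adjusted p = 0.00992, and adjusted p = 0.2 with an estimated correlation). Of 11 abscisic acid genes, 9 rose in the induced line and 6 passed the difference test (9 and 7 adjusted over the list alone), with COR15A at 4.30 ± 0.56, NCED3 at 1.17 ± 0.24, ABI1 at 0.84 ± 0.12 and LTI30 at 2.23 ± 0.28. The median difference was 0.60 (adjusted p = 0.00578, and adjusted p = 0.955 with an estimated correlation). With scan day as a block, 3 abscisic acid members were called, and NCED3 (0.45) and ABI1 (0.49) were not. In the induced line the abscisic acid (adjusted p = 0.093) and wax lists (adjusted p = 0.221) were then not called by cameraPR, while the regeneration list was (adjusted p = 0.00128).

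The other lists were not called in the difference at 24 h. In cytokinin response, 9 of 12 members fell and 1 rose in the induced line (the same adjusted over the list alone), with CRF6 at 1.56 ± 0.18, ARR6 at -0.82 ± 0.17 and LBD3 at -0.85 ± 0.23 (adjusted p = 0.463 for the difference). In cytokinin metabolism, CKX4 (2.31 ± 0.17), LOG4 (1.52 ± 0.17) and LOG1 (1.06 ± 0.19) rose and CKX1 fell by 1.62, 4 members up and 7 down in all, also adjusted over the list alone (adjusted p = 0.948 for the difference). In the auxin list IAA2 (1.06 ± 0.14), the synthesis genes YUC4 (2.49 ± 0.36) and TAA1 (0.72 ± 0.14) rose, 6 members up and 6 down, also adjusted over the list alone (adjusted p = 0.247). In the phloem list SUC2 (1.72 ± 0.13) and HB-8 (0.71 ± 0.10) rose and ACL5 fell by 0.80. There 3 members rose and 4 fell, the median difference of 0.09 and the induced-line median of -0.17 had opposite signs, 3 were higher and 3 lower in the difference (the same adjusted over the list alone), and the adjusted p was 0.496. In the cell cycle list CDKB1;2 (-0.57 ± 0.17), CYCA1;1 (-0.55 ± 0.17) and CDC6 (-0.46 ± 0.14) fell, 14 members down and 1 up (15 and 1 adjusted over the list alone, adjusted p = 0.154 for the difference). The difference was called without induced-line DMSO replicate 4 (-0.50), in a fit on the arrays of that time alone (-0.41) and against the mean wild-type effect of 6 and 24 h (-0.71). With scan day as a block 1 member, higher, was called, and CDKB1;2 (0.32) and CYCA1;1 (0.14) had the opposite sign.

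In the suberin list FAR1 (2.01 ± 0.24) and KCS2 (1.74 ± 0.21) rose and ABCG20 (-2.41 ± 0.33) and CYP86B1 (-2.32 ± 0.35) fell, 4 members up and 7 down (adjusted p = 0.739 for the difference, 3 higher and 7 lower adjusted over the list alone). In the root list the root-hair genes RSL4 (4.27 ± 0.37), EXPA18 (3.46 ± 0.44) and EXPA7 (2.70 ± 0.46) rose and CASP2 (-1.23 ± 0.28) fell, 5 members up and 5 down (adjusted p = 0.864, 3 higher and 5 lower in the difference, also adjusted over the list alone). The immunity list had 3 members up and 7 down, also adjusted over the list alone, with PAD3 at -2.23 ± 0.54, FLS2 at -0.77 ± 0.23 and PROPEP2 at -2.23 ± 0.42 (adjusted p = 0.496). In the ethylene list ACO1 (-0.70 ± 0.17) and ORA59 (-2.24 ± 0.41) fell and the synthesis gene ACS8 (3.29 ± 0.46) rose, 4 members up and 7 down (5 and 8 adjusted over the list alone, adjusted p = 0.468). In the wound and touch list CZF1 (1.34 ± 0.16) and ZAT10 (1.43 ± 0.41) rose and CBF2 (-0.68 ± 0.22) fell, 5 members up and 2 down (5 and 3 adjusted over the list alone). There 3 were higher and 1 lower in the difference, also adjusted over the list alone (median 0.0074, mean 0.08, adjusted p = 0.667).

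In the embryo list LEC2 was at least 2.5-fold higher and OLEO2 rose by 3.06 ± 0.69 (above background on 1 of 4 DMSO arrays), while LEC1 had -0.69 and was not called (-0.78 and called without estradiol replicate 1; 3 higher and 2 lower in the difference, also adjusted over the list alone, median -1.44, adjusted p = 0.894). In the photosynthesis list GAPB (-0.54 ± 0.14), LHCB5 (-0.58 ± 0.16) and LHCA2 (-0.61 ± 0.14) fell, 13 members in all, and the difference was not called (adjusted p = 0.718), but was under quantile normalisation (-0.23) and in the series value table (-0.24). The clock list had ELF4 at -0.51 ± 0.14, RVE1 at 0.66 ± 0.22 and GI at 0.51 ± 0.16 (adjusted p = 0.858, 1 higher and 1 lower in the difference, also adjusted over the list alone). In the detoxification list GSTU9 (-1.14 ± 0.26), CYP710A1 (-1.50 ± 0.45) and OPR1 (-0.92 ± 0.28) fell (adjusted p = 0.247, 1 higher and 4 lower in the difference, also adjusted over the list alone). In the heat list HSP70 rose by 1.90 ± 0.34, HSP21 was at least 1.28-fold higher and HSP18.2 had 0.34 (median -0.01, mean 0.36, adjusted p = 0.718, 1 higher in the difference, also adjusted over the list alone). In the senescence list SGR1 rose by 0.76 ± 0.12, PAO had 0.27 and SAG13 -0.21 (median 0.24, mean -0.21, adjusted p = 0.615, 1 higher in the difference, also adjusted over the list alone).

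At 24 h 9548 genes were called in the induced line, 3895 higher and 5653 lower, and 5668 in the difference, of which 5167 had the same sign in both (9653 were called in the difference in a fit on the arrays of that time alone). Of the calls in the difference 43.1% were higher, with 51.5% under quantile normalisation and in the series value table, and 50.6% of 3756 with normexp. Of the 2682 genes of the induced line with at least a 2-fold change 51.5% were higher, against 40.8% of all its calls. The 2 groups of the induced line were scanned on different days at this time: with scan day as a block 4220 genes were called, 2008 higher and 2212 lower, and with the error taken between slides 2056, 1134 higher and 922 lower. With that block ARR6, LBD3, CKX1, TAA1, SND1, PAD3, FLS2, ACO1, ACS8, CBF2, CDC6, GAPB, GI, RVE1, CYP710A1, OPR1, HSP70, HSP21 and SGR1 were no longer called, while the 10 genes with the largest changes were.

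Over the 5 times, 16 of 110 list tests of the difference were called, 11 higher and 5 lower, and 2 of them, xylem at 12 and 24 h, were called with an estimated correlation. Genes called in the induced line were shared between neighbouring times more often than independent lists of the same sizes: 913 higher genes were shared at 3 and 6 h against 151, 1340 at 6 and 12 h against 230, and 2158 at 12 and 24 h against 495. For lower genes these were 537 against 320, 1491 against 732 and 3092 against 1317. The changes of all genes correlated between times with a median of 0.57 in the induced line and 0.089 in wild type, across genes, which are not independent replicates.

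In wild type, where estradiol has no WIND1 transgene to act on, the comparison asks what the inducer did by itself. At 1 h AT5G44360 rose by 5.01 ± 0.30, and DAZ2 was at least 13-fold, AT5G51610 at least 8.67-fold, CDC20.3 at least 5.72-fold and CYP89A3 at least 4.39-fold higher than in DMSO. Of these, AT5G44360 (-3.95 ± 0.30), AT5G51610 (at least 10.0-fold) and CDC20.3 (at least 5.94-fold) were lower under estradiol at 6 h. The largest falls at 1 h were those of AT1G53600, at background in both groups, GLR2.2 (-1.92 ± 0.48, above background on 1 of 4 estradiol arrays), AT2G07705 (at least 1.94-fold), AT3G59730 (at least 1.67-fold) and AT2G45360 (-1.59 ± 0.40), and the first 4 had the opposite sign with normexp. At 1 h 6266 genes were called, 3863 higher and 2403 lower (61.7% higher, with 52.2% under quantile normalisation, 52.3% in the series value table and 52.5% with the mean over probes), and 3424 in a fit on the arrays of that time alone. By at least 2-fold 1057 were higher and 44 lower. At 3 h THAS1, which makes the triterpene thalianol, rose by 2.36 ± 0.33. AT5G36470 was called higher, above background on 3 of 4 estradiol and 0 of 4 DMSO arrays, too close to background for a bound. AT2G18490, AT5G42500 and AT3G42565 were at least 1.97-fold, 1.41-fold and 1.01-fold higher. The meristem peptide CLV3 was at least 2.43-fold, BLH11 at least 2.52-fold and AT1G23160 at least 1.6-fold lower, and AT1G71691 (-2.33 ± 0.61) and AT3G14981 (-2.30 ± 0.54), each above background on 1 of 4 estradiol arrays, fell. There were 3588 calls at 3 h (48.6% higher, with 55.4% under quantile normalisation, 55.3% in the series value table, 59.2% of 2190 with normexp and 37.8% with the mean over probes), and 2321 without replicate 3 of the estradiol arrays.

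At 6 h the largest wild-type rises were those of dim genes: AT4G14105 was at least 2.3-fold, AT5G20370 at least 1.92-fold, AT5G27170 at least 1.91-fold, AT3G06545 at least 1.78-fold and AT1G66210 at least 1.5-fold higher. AT4G11300 was at least 3.53-fold lower and AT1G55546, above background on 1 of 4 estradiol arrays, fell by 3.45. There were 4357 calls, 2350 higher and 2007 lower, and 2890 without replicate 3 of the DMSO arrays, where AT3G06545 was not called. With normexp there were 2571, 1225 higher and 1346 lower, and of the 563 with at least a 2-fold change 180 were higher and 383 lower. At 12 h CLPB2 was at least 4.92-fold higher, AGL61 rose by 2.62 ± 0.51, and TET14, AT3G62990 and AT3G05950 were at least 1.95-fold, 1.56-fold and 1.28-fold higher. The glutamate-receptor genes GLR2.2 (-2.47 ± 0.48) and GLR2.3 (at least 2.93-fold) were lower, as were AT3G03670 (at least 2.71-fold), AT5G38910 (-2.20 ± 0.75) and AT1G49715 (-2.11 ± 0.53), and these 5 had the opposite sign with normexp. GLR2.2 and AT1G49715 lay above background on 2 of 4 estradiol arrays and AT5G38910 on 1. CLPB2 lost its call without each of 6 single arrays and AT5G38910 without each of 5. There were 2513 calls at 12 h (59.6% higher, with 83.6% of 4450 with normexp, 44.2% with the mean over probes and 43.7% of the 190 with at least a 2-fold change), 1550 without replicate 1 and 1636 without replicate 4 of the DMSO arrays. At 24 h AT4G10265 was at least 4.1-fold higher, AT5G24200 (2.74 ± 0.74), DXPS1 (2.67 ± 0.71), CSLG2 (2.63 ± 0.55) and the calmodulin-like gene CML41 (2.55 ± 0.69) rose, LCR85 was at least 4.15-fold lower, and AT3G02620 (-2.30 ± 0.47), AT1G56710 (-1.82 ± 0.41, above background on 2 of 4 estradiol arrays), AT4G37850 (-1.52 ± 0.35) and AT4G22610 (-1.32 ± 0.27) fell. AT5G24200, DXPS1 and CML41 lost their calls without most single arrays, CSLG2 without estradiol replicate 2 (1.87), AT1G56710 without estradiol replicate 4 (-1.57) and AT4G37850 without DMSO replicate 3 (-1.37). There were 247 calls at 24 h, 196 higher and 51 lower, 1972 in a fit on the arrays of that time alone, 137 under quantile normalisation, 140 in the series value table and 38 with normexp. Without DMSO replicate 2, 3 or 4 there were 111, 117 and 129, and without estradiol replicate 1, 3 or 4 there were 104, 147 and 148. The wild-type groups shared a scan day at 6 and 24 h and not at the other times.

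The lines were compared before treatment to see how the inducible line differed from wild type at 0 h. AT5G24820 was at least 18.1-fold higher in the line, and the seed protease DELTA-VPE (4.53 ± 0.99), the expansin EXPA2 (4.52 ± 0.69) and isocitrate lyase ICL (4.29 ± 0.78) were higher, as was AT5G53270 (at least 5.4-fold). PCC1 (-7.42 ± 0.66), ANK (-5.24 ± 0.77, above background on 1 of 4 arrays of the line), ACD6 (-4.34 ± 0.44) and AT5G42530 (-4.29 ± 0.40) were lower, and the glucanase BGL2, a marker of salicylic acid responses, was at least 20.3-fold lower. The salicylic acid list was lower in the line (12 of 22 members lower and 1 higher, median -0.98, adjusted p = 2.39e-05, and adjusted p = 0.791 with an estimated correlation), with NIMIN1 at -3.51, SARD1 at -2.55 and WRKY54 at -2.07. The embryo list was higher (8 of 11 members, median 3.19, adjusted p = 1.31e-06, and adjusted p = 0.38 with an estimated correlation). WIND1 probes 1 (0.48 ± 0.12) and 6 (0.40 ± 0.13) and AT1G22190 (0.87 ± 0.15) were higher in the line, and the dim AT5G65130, above background on 1 of 4 arrays of the line, was called lower (-0.74 ± 0.23), with array values that overlapped between the groups. In all 5252 genes were called, 2580 higher and 2672 lower (49.1% higher, with 57.9% without the filter on dim probes, 50.4% with the mean over probes and 64.7% of the 1014 with at least a 2-fold change). The groups were scanned on different days: with scan day as a block 3375 genes were called, 1711 higher and 1664 lower, and with the error taken between slides 99, 78 of them higher, without AT5G53270, BGL2, ANK and ACD6.

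Over the DMSO arrays of the 5 times, 20 against 20, AT5G24820 (4.1 ± 0.15, above background on 4 of 20 wild-type arrays), AT4G38410 (3.16 ± 0.12), AT3G05640 (3.11 ± 0.08), CYP71B10 (2.79 ± 0.25, on 3 of 20) and AT3G28600 (2.77 ± 0.16) were higher in the induced line. TCP1 (-2.18 ± 0.15, above background on 5 of 20 induced-line arrays), AT3G56210 (-1.01 ± 0.07) and AT2G21080 (-0.42 ± 0.04) were lower, and TCP1 had 0.02 with normexp. At 24 h, where both DMSO groups shared a scan day, AT5G24820 was at least 8.82-fold higher in the induced line, AT4G38410 differed by 3.16, AT3G05640 by 2.77, PCC1 by -3.14 and AT3G56210 by -1.31, and TCP1 was not called (-0.91). Of the genes named at 0 h, ACD6 (-2.20) and AT5G42530 (-1.97) were also lower there, while DELTA-VPE (1.79), EXPA2 (1.32), ICL (1.37), AT5G53270, BGL2 (-2.47) and ANK (-1.67) were not called. The salicylic acid list was lower over the 5 times (median -0.39, adjusted p = 0.0162) and at 24 h alone (median -0.19, adjusted p = 0.0484), both lost at adjusted p = 0.917 with an estimated correlation. At 24 h 4 of 22 members were lower, PR5 (-1.19), WRKY70 (-1.16), WRKY54 (-1.38) and WRKY38 (-1.39), and NIMIN1 (-1.02) and SARD1 (-0.97) were not called. The embryo list was not called over the 5 times (7 members higher and 2 lower, median 1.16, adjusted p = 0.174). At 24 h alone it was (2 of 11 members higher, median 1.27, adjusted p = 0.0343, and adjusted p = 0.917 with an estimated correlation). The xylem list was higher by a median of 0.24 (adjusted p = 0.00669) over the 5 times and 0.27 (adjusted p = 0.00814) at 24 h, also lost at adjusted p = 0.917 with an estimated correlation. In all 12838 genes were called, 51.1% higher, 68.4% with normexp and 47.1% with the mean over probes, and of the 799 differing by at least 2-fold 47.7% were higher. With scan day as a block there were 4544, and at 24 h alone 3761. At 1, 3 and 6 h the DMSO arrays of the lines also differed in extraction protocol and scan day. The count of 12838 therefore does not separate the lines from these.

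The wild-type DMSO arrays were compared with 0 h to describe the course of the day without estradiol. By the rule for this comparison, the named genes were the defensin PDF1.2 (range 7.94, lowest at 1 h and highest at 12 h), AT5G23240 (7.61, from -5.62 at 0 h to 2.0 at 12 h), NATA1 (6.69, lowest at 1 h and highest at 6 h), DAZ2 and AT5G62360 (6.57, from -3.73 to 2.84 at 6 h). PDF1.2 and NATA1 each lay above background on 1 of 4 arrays at 1 h. The 4 arrays of a group scattered widely for NATA1, with a standard deviation of 5.91 at 0 h and 3.26 at 6 h. Its adjusted p by limma's F test was 0.045. For PDF1.2 the standard deviation was 5.47 at 0 h. The lowest values of PDF1.2, NATA1 and DAZ2 all came from the 1 slide of the 1 h DMSO arrays. DAZ2, at background on all 4 arrays at 1 h, was at least 47.2-fold higher at 6 h. In all 16998 of 21501 genes were called at any time, from 5468 at 1 h to 9196 at 6 h. Between times scanned on 1 day, 7348 genes differed between 12 and 1 h and 5489 between 24 and 3 h. Time of day and time since treatment were not separated by the design.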

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

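The tests of explanations in this part, and the regrouping of treatment within each line, were chosen after the results were seen. The rule for single arrays, the differences between the lines and the probes without a locus were planned.

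The wild-type rises at 1 h were 1057 genes higher by at least 2-fold under estradiol, with a median of 1.60 (log2), among them DAZ2 and CDC20.3. A lasting response to estradiol was argued against by a median effect of -0.157 on these genes at 6 h (0.471 at 24 h). Signal close to background went with the rises: on the untreated 0 h arrays, which did not enter their selection, 42.7% of these genes were not well above background on all 4 arrays, against 6.02% of all genes tested (a first test on the 1 h DMSO arrays, 55.2% against 6.79%, was favoured by the selection). Scan day stayed open under 2 tests, the second written after the outcome of the first was seen: the groups of the estradiol slide's day lay at least 1.19 above the 1 h DMSO arrays and those of other days at most 1.09, while the 12 h DMSO arrays, of the same day as the 1 h ones, also lay 1.09 above them but differed in time, with 7348 genes called between them. A transient response, scan day and the single slide of the 1 h DMSO arrays therefore could not be told apart.

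The xylem list rose in the induced line by a median of 1.22 at 12 h and 1.53 at 24 h, with VND7 and VND2 ahead. A difference between slides of the size seen in wild type was argued against, since the smaller median, 1.22, lay above the wild-type medians of the 5 times (-0.112 to 0.103). At 12 h both groups shared a scan day. At 24 h they did not, and the median was 1.74 with scan day as a block. That block rests on wild-type estradiol against DMSO slides, so it cannot separate scan day from faults of single slides. The phloem and procambium list did not rise as far as the xylem list, with a median of -0.172 at 24 h (0.329 with that block, below xylem by more than the spread of its members, 0.581). Its members were mixed, SUC2 and HB-8 rising and ACL5 falling, and its median changed sign with the block. The list therefore cannot decide on a larger share of vascular tissue as a whole. The photosynthesis (median -0.425) and root lists (-0.303) fell at 24 h, so a lower share of other tissues stays open. A response of xylem genes to WIND1 may underlie the rise, as a hypothesis found and tested on the same arrays. A fault of the 12 h and 24 h slides larger than any seen in wild type stays open, since each group lay on 1 slide.

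The induced-line calls at 1 h numbered 5676, and replicate 2 of the DMSO arrays had a median signal of 63.9, against 291 to 338 in its group, with 66.6% of spots well above background against 73.6% to 75.1% and a spike-in slope of 0.823 against 0.926 to 0.941. Without that array 1570 genes were called, 803 higher and 767 lower, and 1246 of them were among the 5676 (22% kept), so that 1 weak array went with most of the calls. Leaving out an array also lowers the number of samples, and the other counts at this time without 1 array of the induced line reached 7199. Handling at treatment, shared by both lines, could not be told apart from induction, since the wound and touch list missed the threshold in the difference (adjusted p = 0.095) with medians of 0.94 in the induced line and 0.57 in wild type, and without wild-type estradiol replicate 1 (median difference 0.50) or induced-line estradiol replicate 1 (0.46) or 4 (0.44) the difference was called.

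Of 176 groups of 4 values, 15 held an array far from the other 3, where chance gives about 1 in 20 groups, 8.8 here. The median signal stood apart in 6 groups: 488.9 on wild-type 3 h DMSO replicate 1 (others 626.5 to 636.9), 628.3 on wild-type 24 h DMSO replicate 1 (545.6 to 545.9), 509 on wild-type 3 h estradiol replicate 2 (396.9 to 401.1), 638.8 on wild-type 12 h estradiol replicate 1 (455.2 to 474), 63.86 on induced-line 1 h DMSO replicate 2 (291.4 to 338) and 275.5 on induced-line 6 h DMSO replicate 1 (339.2 to 351.2). The percent of spots well above background was 75 on wild-type 3 h estradiol replicate 3 (77.09 to 77.52).

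WIND1 probe 2 stood at 1.905 on replicate 4 of the untreated induced line (others 2.177 to 2.207). Probe 3 stood at -0.9051 on induced-line 1 h estradiol replicate 4 (-1.412 to -1.342). Probe 4 stood at 4.558 on the weak induced-line 1 h DMSO replicate 2 (3.226 to 3.287) and at 3.285 on induced-line 3 h estradiol replicate 2 (3.443 to 3.47). Probe 5 stood at -2.288 on wild-type 12 h estradiol replicate 3 (-1.997 to -1.945) and at -2.006 on induced-line 24 h estradiol replicate 2 (-1.724 to -1.7). Probe 6 stood at 1.5 on wild-type 24 h DMSO replicate 3 (1.162 to 1.187) and at 0.7967 on wild-type 1 h estradiol replicate 3 (0.9327 to 0.9461).

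The estradiol effect differed between the lines, by limma's test of the difference, for 4117 genes at 1 h, 1208 at 3 h, 4363 at 6 h, 5626 at 12 h and 5668 at 24 h. Of the 9418 probes without a locus, which no comparison used apart from the fit of all probes for WIND1 and its homologues, 5709 lay well above background on all arrays of a group. Among them 300 at 1 h, 195 at 3 h, 384 at 6 h, 797 at 12 h and 1099 at 24 h were called in the induced line and in the difference with 1 sign.

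Other splits of the same arrays were counted over the 21306 genes without missing values. For the 4 against 4 comparisons chance could be excluded, since 1 of 35 splits, the real one, gave as many calls. In the induced line the real count and the highest of the other splits were 5614 and 2825 at 1 h, 3954 and 1567 at 3 h, 4908 and 3918 at 6 h, 7669 and 3603 at 12 h, and 9456 and 3753 at 24 h. In wild type they were 6200 and 1589, 3554 and 342, 4315 and 344, 2473 and 248, and 243 and 5, in the same order of times, and between the lines at 0 h 5197 and 1179. Over the DMSO arrays (12719 and 3151) and the time course (16838 and 4777) 1 of 100 draws, the real one, gave as many, and chance could be excluded. These splits do not separate treatment from slide, since each group lay on 1 slide.

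For the difference, draws over all 4 groups gave as many calls in 16, 13, 13, 6 and 7 of 100 at 1, 3, 6, 12 and 24 h, so chance could not be excluded that way. The highest other draws had 9736, 8677, 8590, 6974 and 7253 calls against 4079, 1200, 4317, 5576 and 5619. Counts so far above the real ones at 1, 3 and 6 h point to a structure of the samples. Draws of treatment within each line, added after that outcome, gave as many in 6, 2, 1, 2 and 4 of 100, the real grouping included. These draws cannot exclude chance either, since they were chosen after the first outcome. Only the real grouping follows the slides, so a difference between slides would also raise its count. Their highest other counts were 6452, 1834, 3783, 6301 and 6087.

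For the lists, 2, 0, 3, 5 and 6 were called in the difference with adjustment within each time by cameraPR, where 3 had an unadjusted p under 0.05 at 3 h. Over all 4 groups 73, 100, 79, 80 and 53 of 100 draws gave as many, with at most 9, 15, 12, 14 and 10 lists. Within each line 76, 100, 95, 78 and 46 draws did, with at most 10, 16, 12, 15 and 12. At 3 h the real number was 0, so that every draw had to reach it and the test says nothing. At the other times chance could not be excluded for the number of lists called, and draws with several times the real number point to a structure of the samples.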

How the results depend on the processing

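The fits with the error between slides, with scan day as a block, against the mean wild-type effect of 6 and 24 h, between groups of 1 scan day and on the lists in the induced line were chosen after seeing the data. A planned block of slide or scan date could not be fitted without pooling, since every group lay on 1 slide and 1 day, and was not run. For the changes below the cause was not tested, except that a 2-fold threshold, fewer arrays, fewer degrees of freedom and other contrasts by construction ask another question or keep fewer genes. Of 605 named gene results, 11046 values under alternatives held 10252 on the same side of the threshold, with the same direction if called. Another 696 were weaker, 73 stronger and 25 reversed, and of 110 list results, 2860 values held 2782, 38, 34 and 6 in that order. A change of sign between values that were not called counted as the same. Signal over background limited genes at background in 1 group to a lower bound. Normexp, run on the median spot intensity in place of the processed signal and so changing 2 choices at once, reversed 13 of the 605 named results and weakened 74.

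With quantile normalisation wild type at 24 h had 137 calls, GSTU19 had -0.0039 in the induced line at 3 h and the photosynthesis difference at 1 h was -0.0096. The series value table gave 140, -0.00018 and -0.0097. Normexp gave 3116, 2217 and 3275 calls in the induced line at 1, 3 and 6 h, 2190, 2571, 4450 and 38 in wild type at 3, 6, 12 and 24 h, and 2570, 586, 2706, 10221 and 3756 in the difference at the 5 times. It reversed AT1G53600 (0.48), GLR2.2 (0.046), AT2G07705 (0.23) and AT3G59730 (0.25) in wild type at 1 h, AT3G03670 (0.60), GLR2.2 (0.058), GLR2.3 (0.62), AT5G38910 (0.67) and AT1G49715 (0.54) in wild type at 12 h, VND5 (-0.32), LEC2 (-0.84) and FUS3 (-0.78) in the induced line at 12 h, and TCP1 between the lines (0.019).

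The mean over probes gave WIND1 0.99, 1.07 and 1.27 in the induced line at 1, 3 and 6 h, opposite to its brightest probe, and RAB18 0.80 at 12 h. Only the arrays of that time gave 1013 calls in the induced line at 1 h, 3424 and 1972 in wild type at 1 and 24 h, and 1118 and 9653 in the difference at 1 and 24 h. A 2-fold threshold kept 504, 674, 1453, 2099 and 2682 in the induced line, 1101, 286, 563, 190 and 127 in wild type, 1061, 478, 1455, 1994 and 2588 in the difference, 1014 at 0 h and 799 over the DMSO arrays. An estimated correlation kept 2 of 16 lists, and at the preset correlation 25 were called in the induced line. A replicate block, shared by all groups and so unable to take up pairing within a time, left 604 of 605 named results on their side, PXY at 12 h excepted. It gave 5663, 3968, 4960, 7752 and 9556 calls in the induced line.

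Error between slides gave 4, 139, 676, 956 and 2056 in the induced line and 99 at 0 h, and kept 306 of 547 named calls or non-calls. A scan-day block gave 4220 in the induced line at 24 h and 3375 at 0 h. It gave 4544 for the line's DMSO arrays of 12 and 24 h against wild-type arrays of both treatments. It reversed YUC8 (-0.11), AOS (-0.13), CYCA1;1 (0.14), CDKB1;2 (0.32) and CER6 (-0.050) in the induced line at 24 h. Against the mean wild-type effect of 6 and 24 h the difference had 6299 calls at 1 h and 4976 at 3 h, cell cycle -0.52 at 1 h, and photosynthesis -0.051, 0.44 and 0.12 at 1, 3 and 12 h. Within 1 scan day, 3761 genes differed between the DMSO arrays at 24 h, 7348 between 12 and 1 h and 5489 between 24 and 3 h.

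Leaving out 1 array gave 1570 to 7199, 2607 to 4487, 3485 to 5425, 6249 to 7837 and 8090 to 9151 in the induced line, 5176 to 6280, 2321 to 3337, 2890 to 4162, 1550 to 2269 and 104 to 244 in wild type, and 3051 to 5312, 877 to 1298, 3611 to 4363, 4693 to 5963 and 4772 to 5580 in the difference. It gave 4037 to 5042 at 0 h, 12625 to 13594 over the DMSO arrays, 16562 to 16841 in the time course and 14 to 18 lists. Shifts over 1.5 times came in the induced line without 1 h DMSO replicate 2 (1570, with KCR1, -0.53 at the lowest without other arrays, reversed at 0.0054) and 3 h estradiol replicate 4 (2607). In wild type they came without 3 h estradiol replicate 3 (2321), 6 h DMSO replicate 3 (2890), 12 h DMSO replicates 1 and 4 (1550 and 1636), 24 h DMSO replicates 2, 3 and 4 (111, 117 and 129) and 24 h estradiol replicates 1, 3 and 4 (104, 147 and 148).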

Other observations

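The split of the xylem list and the lists in the induced line by itself were chosen after results had been seen, and the lists between the lines were described without a plan. In the cytokinin response list, 7 of 12 members fell in the induced line at 1 h (8 down and 2 up adjusted over the list alone, median -0.42, adjusted p = 0.00728, and adjusted p = 0.576 with an estimated correlation). ARR15 fell by 1.23 ± 0.25 at 1 h, 1.32 at 3 h and 1.13 at 12 h. CRF6 rose by 0.94 ± 0.18 at 3 h and 1.64 at 12 h. In cytokinin metabolism LOG7 fell by 1.35 ± 0.22 at 6 h and 1.26 at 24 h, while CKX4 rose by 2.36 ± 0.17 at 6 h. In the auxin list IAA19 rose by 0.95 ± 0.20 and TAA1 fell by 0.58 at 1 h (-0.31 and not called without the weak DMSO replicate 2), with 7 members up and 1 down (8 and 1 adjusted over the list alone, adjusted p = 0.0261, and adjusted p = 0.676 with an estimated correlation). In the suberin list KCS2 (0.97 ± 0.21) and GPAT7 (1.16 ± 0.33) rose at 1 h, 6 members in all (7 adjusted over the list alone, adjusted p = 0.00123, and adjusted p = 0.676 with an estimated correlation), and GPAT7 fell by 1.61 at 6 h. The calmodulin-like gene CML37 of the wound and touch list rose by 2.66 ± 0.50 at 1 h. The root-hair regulator RSL4 rose by 1.24 ± 0.37 at 3 h, 1.22 at 6 h (0.96 and not called without estradiol replicate 4) and 2.68 at 12 h, the clock gene RVE1 by 1.23 ± 0.22 at 1 h and 1.08 at 6 h, and the zinc-finger gene CZF1 by 0.90 ± 0.16 at 3 h and 1.40 at 12 h. The camalexin enzyme gene CYP71A13 rose by 4.58 ± 1.30 at 6 h, where 1 of 4 DMSO arrays lay above background, and CYP71A12 was at least 8.76-fold lower at 24 h.

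In wild type the detoxification list rose at 1 h (9 of 17 members, 10 adjusted over the list alone, median 0.89, adjusted p = 0.0203, and adjusted p = 0.976 with an estimated correlation), and the cell cycle list fell at 3 h (9 of 21, 10 adjusted over the list alone, median -0.35, adjusted p = 0.000352) and rose at 6 h (11 of 21, and 14 up and 1 down adjusted over the list alone, median 0.45, adjusted p = 4.64e-05). Both cell cycle calls were lost at adjusted p = 0.976 with an estimated correlation. The wild-type median of the detoxification list was positive at each of the 5 times, from 0.3 to 0.892. In the induced line that median was 0.41 at 1 h and -0.436 at 24 h. Before treatment the abscisic acid list (6 of 11 members, median 0.73, adjusted p = 0.00238), the suberin list (5 of 13, median 0.57, adjusted p = 0.0093), the wound and touch list (6 of 16, median 0.39, adjusted p = 0.00669), the ethylene list (6 of 18, median 0.42, adjusted p = 0.0343) and the xylem list (5 up and 1 down of 20, median 0.29, adjusted p = 0.0343) were higher in the induced line than in wild type, on slides of different scan days. With an estimated correlation these 5 calls were lost, at adjusted p = 0.757 for abscisic acid and adjusted p = 0.917 for the other 4. At 24 h under DMSO, on 1 scan day, the abscisic acid (0.57, adjusted p = 0.00161) and xylem lists were higher (adjusted p = 0.757 and 0.917 with an estimated correlation), and the suberin (0.26, adjusted p = 0.245), wound and touch (0.30, adjusted p = 0.755) and ethylene lists (-0.015, adjusted p = 0.585) were not called. Over the DMSO arrays the photosynthesis list was lower (15 of 19, median -0.34, adjusted p = 4.6e-05), and the detoxification list (13 of 17, median 0.46, adjusted p = 0.0104) and the regeneration list (11 up and 1 down of 22, adjusted p = 0.00669) were higher. These calls were lost at adjusted p = 0.917, 0.917 and 0.801 with an estimated correlation. At 24 h alone the photosynthesis list had 1 of 19 members lower (median -0.14, adjusted p = 0.0484), the detoxification list 3 of 17 higher (0.66, adjusted p = 0.0122), and the regeneration list was not called (0.17, adjusted p = 0.174). With an estimated correlation the photosynthesis and detoxification calls at 24 h were lost too (adjusted p = 0.921 and 0.917). With scan day as a block, the lists called in the induced line at 24 h were xylem (median 1.74, adjusted p = 2.34e-27), regeneration (0.89, adjusted p = 0.00128), jasmonate (1.43, adjusted p = 0.00454) and photosynthesis (-0.49, adjusted p = 0.00584). The abscisic acid list (0.61, adjusted p = 0.093), the salicylic acid list (-0.49, adjusted p = 0.186) and the wax list (0.20, adjusted p = 0.221) were not called.

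In the xylem list, transcription factors may have changed before wall and cell-death genes, a hypothesis formed after the members had been seen. At 6 h 5 of 11 transcription factors, VND2, VND7, VND6, MYB46 and MYB83, and 0 of 9 other members were higher by limma in both the induced line and the difference (two-sided Fisher exact p = 0.0379). At an unadjusted p under 0.05 the other members also numbered 0. XCP1 rose by 0.54 in the induced line without passing the difference test, and by the induced line alone the numbers were 5 and 1 (exact p = 0.157). Genes of 1 list are not independent, and the test was run on the data that prompted it.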
